A study of Mus musculus with 4 samples.

How the data were processed

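Total RNA from the livers of 4 fasted male mice was labelled with biotin as cRNA and hybridised to one-colour Affymetrix arrays, per the labels' protocols. The labels call the samples of each genotype biological replicates. They give 2 wild-type and 2 Cnot3+/- mice, all 12 weeks old and without food for 24 h, and they do not describe the Cnot3 allele further. The deposited table holds log2 expression values that the authors made with RMA, per the submitters' processing notes. RMA is a general method that corrects background, normalizes across arrays and summarises the probes of each probe set, and it shrinks differences of dim probe sets. The version of RMA, and which arrays it normalized together, are not given in the sources used here. No scanner files were used here. The log2 scale and the absence of gene centring were taken from the values, which ran from 1.85 to 14.96. All 4 columns of values were mapped to their samples, and 0 columns were left over.

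Probe sets were named through the array platform's annotation table, whose symbols can be old. Of 45101 probe sets, 34958 had 1 gene symbol, 932 had several and 9211 had none there. Through their Entrez identifiers, 34754 probe sets matched the mouse gene table of assembly GRCm38.p6, and 0 symbols changed. Only probe sets with 1 symbol were used for genes. No genome coordinates are given, since the build behind the array annotation is not given in the sources used here. The gene table served only for names and for the order of neighbouring genes.

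The deposited values were used without further normalization. Probe sets in the lowest 40% of mean log2 value over the 4 arrays (below 4.06) were left out, which kept 27060. Each gene was then represented by its probe set of highest mean, and a probe set of the kinds that can match several transcripts (_x_at or _s_at) was used only where the gene had no other. This gave 13379 genes, 381 of them through such a probe set. Array values compress large ratios and cannot separate near-identical transcripts, which bears on the Saa, Orm, Gbp and Hspa1 genes.

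The Cnot3+/- arrays were compared with the wild-type arrays in limma 3.58.1 (R 4.3.3), with lmFit and eBayes, two-sided, over all 4 arrays and with no covariate. Adjusted p is by Benjamini-Hochberg, over the genes tested or over the lists, with a threshold of 0.05. Some p-values of genes are also given adjusted over the members of 1 list alone. That adjustment is not corrected for the 45 lists searched, and a member passing only in this way is not counted as a call. The fit had 2 residual degrees of freedom per gene, and the prior added 3.17 (prior SD 0.162). Differences are Cnot3+/- minus wild-type on the log2 scale, SE is the moderated standard error, and intervals cover 95%. The p-values of genes rest on the spread between these few animals and, for the larger part of the degrees of freedom, on that prior. A simulation on the 13379 genes of this comparison, with 50 genes changed at each size, recovered 14% of genes changed by 1 on the log2 scale, 92% of those changed by 2, 98% by 3 and 100% by 4, with 4 false calls. It drew independent normal errors, with the same spread on all 4 arrays for a given gene. It also changed 200 genes, which eases the adjusted threshold. In the data 2 genes passed, and the Cnot3+/- arrays lay further apart than the wild-type arrays. The recovered shares therefore need not hold for real changes here.

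A set of 45 gene lists for pathways, complexes and cell types of the liver was tested with limma's camera at its preset correlation of 0.01 between genes. Camera with a correlation estimated per list, and limma's fry, were the alternatives. Camera asks whether a list's genes rank higher or lower than the other genes. With the preset correlation its p-value rests more on the number of genes than on the spread between animals. In the simulation with no change, 0 of the 45 lists passed. The simulation drew each gene's error independently, while the correlation estimated in the data reached 0.961 for the macrophage list. It therefore does not check how often correlated lists are called falsely. A list raised by 1 on a single array reached an adjusted p of 1.12e-06 with the preset correlation and an unadjusted p of 0.298 with an estimated one, so a preset call can rest on a single array, and the means of the lists that passed are given per array for this reason.

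The genes named are Cnot3 and other subunits of its complex; the 10 genes of largest difference in each direction among those past the threshold, filled up with the largest differences among genes whose groups do not overlap; up to 4 members of each list described, or the 2 largest where fewer than 2 pass; and a fixed set of fasting and lipid genes. Gene models without a proper symbol were left out, and genes outside the rule are said to be so where they appear. The design, the gene lists, the naming rule and most alternatives were set before the data were examined. The alternatives were no filter and a 60% filter on dim probe sets, quantile normalization, centring of each array, averaging of a gene's probe sets, each probe set on its own, a trended or robust prior, no moderation, the replicate number as a block, other thresholds, and leaving out each array in turn. Values of the individual lists under the filter, scaling, probe set, block and left-out-array settings were added after the data were seen. No batch, slide or scan date is given in the sources used here.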

Results

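Liver RNA was profiled on 4 one-colour Affymetrix arrays, each carrying biotin-labelled cRNA from the total RNA of 1 male C57BL/6J mouse. The mice were 12 weeks old, ate normal chow and had gone without food for 24 h before the liver was taken. There were 2 wild-type animals and 2 animals labelled Cnot3+/-, which carry 1 altered copy of Cnot3 by their label. The arrays are called wild-type 1, wild-type 2, Cnot3+/- 1 and Cnot3+/- 2 after their labels. Cnot3 encodes a subunit of the CCR4-NOT complex, which shortens the poly(A) tails of mRNAs. The comparison asks which liver transcripts differ between the genotypes in the fasted state. Each array gave 45101 probe set values, and 13379 genes were tested through 1 probe set each. The number of arrays, 2 per group, limits the precision of every value.

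The 4 arrays had similar distributions, with median log2 values between 4.62 and 4.66. Over the genes tested, 74 genes lay at least 2-fold apart between the wild-type arrays, and 432 between the arrays labelled Cnot3+/-. Cnot3+/- 2 stood furthest from the rest, with 391 genes at least 2-fold apart from wild-type 1 and 321 from wild-type 2. The corresponding numbers for Cnot3+/- 1 were 158 and 128. No pair of arrays held identical values. The 3′ minus 5′ log2 signal of the Actb control probe sets lay between 1.46 and 1.60 on the 4 arrays. For Gapdh it lay between 0.11 and 0.31.

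Cnot3 itself was not lower in the arrays labelled Cnot3+/-. Its log2 values were 7.48 in wild-type 1, 8.14 in wild-type 2, 7.70 in Cnot3+/- 1 and 7.86 in Cnot3+/- 2. The difference was -0.03 (SE 0.25, n = 2 per group, limma adjusted p = 1), with a 95% confidence interval from -0.66 to 0.60 that leaves out a fall by a factor of 2. The direction turned to 0.30 without wild-type 2 and to 0.05 without Cnot3+/- 1. A dimmer Cnot3 probe set differed by 0.11 (SE 0.14). The labels do not say which part of the gene was targeted, nor where the probes lie. Probes outside the altered part need not show a change. This measurement therefore does not bear out the genotype labels, and each direction given here rests on the arrays as labelled.

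The other CCR4-NOT subunits stood close to wild-type. Differences of the 9 other Cnot genes tested ran from -0.25 (SE 0.22) for Cnot8 to 0.24 (SE 0.13) for Cnot10, and none had an adjusted p below 0.999. Cnot8 ran from -0.48 without wild-type 2 to -0.02 without wild-type 1. In the CCR4-NOT list, which also holds the BTG and TOB partners of the complex, 8 of 15 genes were higher and 7 lower (camera adjusted p = 0.470). Its largest difference was that of Btg2, an antiproliferative gene whose protein binds the deadenylase subunits, at 0.95 (SE 0.23, adjusted p = 0.999). A further list of 28 other mRNA decay factors had 18 genes higher, with means of 0.11 above wild-type in Cnot3+/- 1 and 0.10 in Cnot3+/- 2 (adjusted p = 0.0193 with the preset correlation, adjusted p = 0.703 with an estimated correlation). Wild-type 1 and wild-type 2 lay at -0.08 and 0.08, so wild-type 2 stood nearly as high as the Cnot3+/- arrays. The GW182 genes Tnrc6b and Tnrc6c, which link microRNA complexes to CCR4-NOT, differed by 0.46 (SE 0.23) and 0.39 (SE 0.14). Tnrc6b differed by 0.16 without wild-type 1 and 0.77 without wild-type 2. The decay factor call was lost without wild-type 1 (adjusted p = 0.449) and without Cnot3+/- 1 (adjusted p = 0.229).

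Lcn2 and Cox6b2 rose, and no gene fell past the threshold. Lcn2 encodes lipocalin 2, an iron-siderophore-binding acute phase protein. It was 18.6-fold higher in the arrays labelled Cnot3+/- (95% confidence interval 14.5 to 23.8; log2 difference 4.22, SE 0.14, n = 2 per group, limma adjusted p = 0.00687), with log2 values of 5.40 and 5.40 in wild-type and 9.52 and 9.71 in Cnot3+/-. Cox6b2 encodes a cytochrome c oxidase subunit best known from testis. It was 10.8-fold higher (interval 8.37 to 14.0; log2 difference 3.44, SE 0.15, adjusted p = 0.0126), at 4.53 and 4.45 in wild-type and 8.04 and 7.82 in Cnot3+/-. These wild-type values lie below the median of every array and no detection call was used, so its fold and interval are those of the RMA values and need not be those of the transcript. Cox6b2 lies 21 tested genes from Cnot3 in the gene order of assembly GRCm38.p6.

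Among genes higher in the Cnot3+/- arrays, the smallest adjusted p after these 2 was 0.423, for Orm2. Among genes lower there, the smallest was 0.997 in limma. At an unadjusted p under 0.05 there were 232 higher and 248 lower genes, 480 in all, where chance alone gives 669. The groups were fully separated in 31.5% of genes, where chance gives 33.3%. With limma's moderation of variances left out, Lcn2 had an adjusted p of 0.548 and Cox6b2 of 0.722. Neither passed in 3 arrays without wild-type 1 (adjusted p = 0.967 for Lcn2 and 1 for Cox6b2) or without wild-type 2 (0.678 for both). The differences themselves hardly moved when any 1 array was left out, from 4.12 to 4.31 for Lcn2 and from 3.33 to 3.55 for Cox6b2.

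Of the genes whose groups did not overlap, 43 were at least 2-fold higher and 9 at least 2-fold lower, and apart from Lcn2 and Cox6b2 these are values without a call. Leaving out an array sets 1 array against 2, where non-overlap is easier to reach by chance. Counts with an array left out can be larger for that reason alone. Without Cnot3+/- 1 the number of higher genes was 289, and without Cnot3+/- 2 the number of lower genes was 66. It was 72 and 83 higher, and 15 and 35 lower, without wild-type 1 and 2, and 20 lower without Cnot3+/- 1. The largest higher values were those of Saa2 at 3.98 (SE 0.60), Moxd1, a monooxygenase-like gene, at 3.21 (SE 1.43), and Saa1 at 3.02 (SE 0.55). Next came the interferon-induced GTPase gene Gbp6 at 2.39 (SE 1.25), the metallothionein gene Mt2 at 2.29 (SE 0.60), Orm2 at 2.20 (SE 0.20), Usp18 at 2.16 (SE 0.35) and the macrophage scavenger receptor gene Marco at 2.16 (SE 0.97). Moxd1 stood at 10.31 in Cnot3+/- 1 and 6.08 in Cnot3+/- 2, against 5.85 and 4.11 in wild-type. Its difference was 1.10 without Cnot3+/- 1 and 5.33 without Cnot3+/- 2. Gbp6 stood at 6.07 in Cnot3+/- 1 and 10.08 in Cnot3+/- 2, and differed by 0.39 without Cnot3+/- 2 and 4.40 without Cnot3+/- 1. Marco differed by 0.61 without Cnot3+/- 2 and 3.70 without Cnot3+/- 1. Mt2 differed by 1.46 without Cnot3+/- 1.

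The largest lower values were smaller in size. Zfp979 differed by -1.39 (SE 0.25), the hepatic peptide gene Leap2 by -1.20 (SE 0.41), and the organic anion transporter gene Slco1a4 by -1.18 (SE 0.14). Srebf1, which encodes the lipogenic transcription factor SREBP1, differed by -1.15 (SE 0.23). Aatk differed by -1.14 (SE 0.16), Cnmd by -1.08 (SE 0.51), Nxpe2 by -1.07 (SE 0.18), Nlrp12, a neighbour of Cnot3, by -1.06 (SE 0.25) and Clec4g, a sinusoidal endothelial lectin gene, by -0.99 (SE 0.39). Hsd3b3 differed by -1.01 (SE 0.28) on the probe set used and by -0.03 on a second one. Cnmd and Clec4g differed by -1.84 and -0.39 without Cnot3+/- 1, and by -0.32 and -1.59 without Cnot3+/- 2. Leap2 differed by -0.64 without wild-type 1. None of these had an adjusted p below 0.997.

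**Figure D1:**
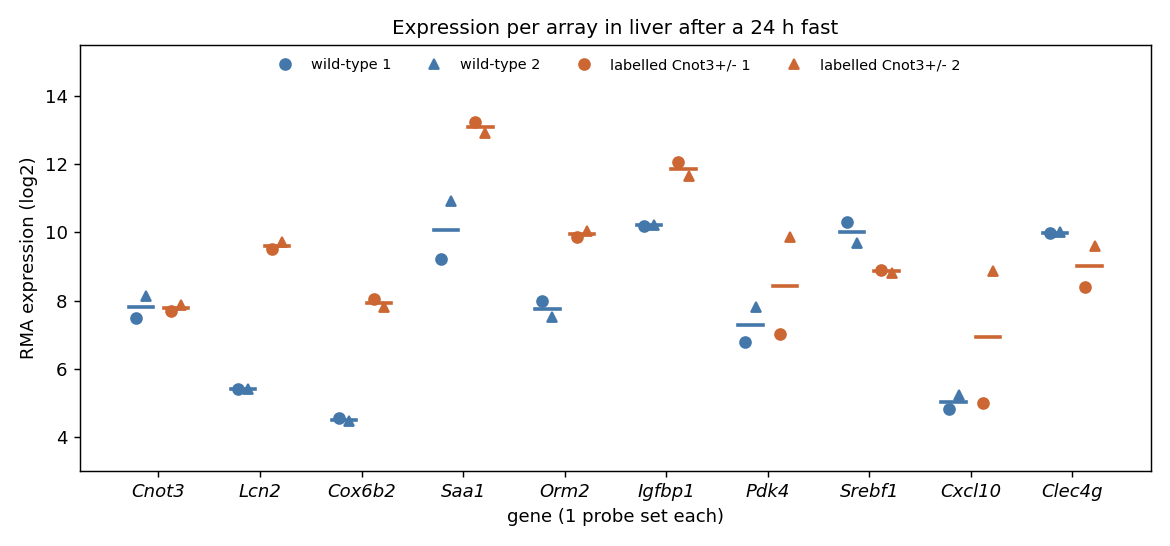
Log2 RMA expression (vertical axis) of 10 genes (horizontal axis, 1 probe set each) on each of the 4 arrays, with circles for replicate 1, triangles for replicate 2, blue for wild-type, orange for arrays labelled Cnot3+/- and bars for the mean of 2. Lcn2 lies at 5.40 in both wild-type arrays and at 9.52 and 9.71 in the Cnot3+/- arrays, while Cxcl10 is high only in Cnot3+/- 2, at 8.88.

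Genes of the acute phase response stood higher in both arrays labelled Cnot3+/-. This list of liver-made plasma proteins and their regulators had 24 of 25 genes higher and 15 of them with no overlap between the groups. The list mean lay 0.96 above the wild-type mean in Cnot3+/- 1 and 0.81 above it in Cnot3+/- 2, with the wild-type arrays at -0.07 and 0.07. The mean difference was 0.88 and the median 0.37. The list passed with the preset correlation (camera adjusted p = 3.81e-16), and had an adjusted p = 0.703 with an estimated correlation. Without its 4 members of largest difference the list mean was 0.42 (adjusted p = 4.97e-09 with the preset correlation, unadjusted p = 0.0542 with an estimated one), a setting chosen after the values were seen.

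Adjusted over the list alone, 7 acute phase genes passed, against Lcn2 alone among its members when adjusted over all genes tested. Adjustment over 1 list is not corrected for the other lists. The other members that passed in this way were the serum amyloid A genes Saa1 and Saa2, the orosomucoid genes Orm1 at 0.61 (SE 0.13) and Orm2, the amyloid P component gene Apcs at 1.16 (SE 0.28), and the protease inhibitor gene Serpina3n at 0.90 (SE 0.18). Orm1, Apcs and Serpina3n were named after their values were seen. Saa1 and Saa2, and likewise the Orm genes, are close in sequence, so their probe sets may read each other's transcripts. The neutrophil list, of which Lcn2 is also a member, had 6 of 11 markers higher and 5 lower, with a median difference of 0.02 (adjusted p = 0.326, and 0.00218 with the lowest 60% of probe sets left out). Adjusted over the list alone, Lcn2 was the member that passed. The calgranulin gene S100a8 differed by 0.83 (SE 0.59), from 4.38 and 3.74 in wild-type to 4.02 in Cnot3+/- 1 and 5.76 in Cnot3+/- 2. Macrophage markers did not follow the acute phase genes across the Cnot3+/- arrays, standing at -0.26 in Cnot3+/- 1 and 1.63 in Cnot3+/- 2 relative to the wild-type mean.

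Genes that insulin represses through the transcription factor FOXO1 also stood higher in both Cnot3+/- arrays. Of 18 genes, 15 were higher, and the list mean lay 0.36 and 0.38 above the wild-type mean (adjusted p = 0.000287 with the preset correlation, adjusted p = 0.703 with an estimated correlation). The wild-type arrays lay at -0.11 and 0.11. Igfbp1, which encodes an insulin-like growth factor binding protein made in fasting liver, was 3.16-fold higher (log2 difference 1.66, SE 0.18), at 10.20 and 10.23 in wild-type and 12.07 and 11.67 in Cnot3+/-. Its adjusted p was 0.667 over all genes tested. It was 0.00359 adjusted over the list alone, without correction for the other lists, and Igfbp1 was the member that passed there. Pdk4, whose kinase restrains pyruvate dehydrogenase in fasting, differed by 1.15 (SE 0.94), at 6.77 and 7.80 in wild-type, 7.03 in Cnot3+/- 1 and 9.85 in Cnot3+/- 2. Its difference was -0.26 without Cnot3+/- 2. The list call was lost without wild-type 1 (adjusted p = 0.0534).

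The gluconeogenesis list did not pass the test. Of 17 genes, 11 were higher, with a mean difference of 0.21 (adjusted p = 0.0543). Ppargc1a, a coactivator of fasting genes, differed by 1.13 (SE 0.29) and the tyrosine aminotransferase gene Tat by 0.56 (SE 0.27). The rate-setting enzyme genes Pck1 and G6pc differed by 0.20 (SE 0.16) and 0.27 (SE 0.23). G6pc differed by -0.02 without wild-type 1. Without that array Ppargc1a differed by 0.73, Tat by 0.20 and Pck1 by 0.05, and without wild-type 2 by 1.54, 0.92 and 0.35. The list passed without wild-type 2 (adjusted p = 0.00216), without Cnot3+/- 2 (0.00782), with no filter on dim probe sets (0.0226), after quantile normalization (0.0451) and with a gene's probe sets averaged (0.0476).

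Lipogenic genes had values below wild-type without a call. In the fatty acid synthesis list 12 of 19 genes were lower, with a mean difference of -0.18 (adjusted p = 0.0875). Besides Srebf1, the elongase gene Elovl6 differed by -0.86 (SE 0.24), the fatty acid synthase gene Fasn by -0.46 (SE 0.27), and the desaturase gene Scd1 by -0.24 (SE 0.13) on one probe set and -0.85 on another. Fasn ran from -0.75 without Cnot3+/- 2 to -0.16 without Cnot3+/- 1, and Elovl6 was -0.57 without wild-type 2. The list passed without wild-type 1 (adjusted p = 0.000113) and without Cnot3+/- 2 (0.0402), and turned upward without wild-type 2 (0.934). It also passed with the lowest 60% of probe sets left out (0.0217) and with probe sets averaged (0.0484). In the glycolysis and glycogen list 12 of 14 genes were lower (mean -0.14, adjusted p = 0.0718), among them the liver pyruvate kinase gene Pklr at -0.60 (SE 0.25) and the glucose transporter gene Slc2a2 at -0.46 (SE 0.13). Pklr was -0.33 without Cnot3+/- 1 and -0.38 without wild-type 2. That list passed with the lowest 60% of probe sets left out (adjusted p = 0.0355) and with probe sets averaged (0.0484).

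Genes of fatty acid oxidation and ketogenesis, the targets of PPARalpha in fasting, lay near wild-type on average. Of 34 genes, 22 were lower and 12 higher, with a mean difference of -0.06 (adjusted p = 0.145). The list mean lay at -0.24 in Cnot3+/- 1 and 0.12 in Cnot3+/- 2, with the wild-type arrays at -0.06 and 0.06. The carnitine palmitoyltransferase gene Cpt1a differed by 0.06 (SE 0.13), Cyp4a14 by 0.07 (SE 0.13), Angptl4 by 0.03 (SE 0.14) and the hormone gene Fgf21 by 0.02 (SE 0.41). The largest differences in the list were those of Pdk4 and of the acyl-CoA thioesterase gene Acot3, at -0.61 (SE 0.60). Acot3 turned to 0.03 without wild-type 2 and 0.07 without Cnot3+/- 1. The list passed downward without Cnot3+/- 2 (adjusted p = 0.000944) and turned upward without Cnot3+/- 1 (0.454).

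Respiratory chain genes had 31 of 43 members lower, with a mean difference of -0.06 (adjusted p = 0.110). That list passed without Cnot3+/- 1 (adjusted p = 0.0142) and with the lowest 60% of probe sets left out (0.0407), and turned upward without Cnot3+/- 2 (0.886). In the TCA cycle list 11 of 20 genes were lower (adjusted p = 0.899), and the sign of its test varied between settings. The lipid droplet and lipolysis list had 14 of 24 genes lower (adjusted p = 0.854), among them the lipase inhibitor gene G0s2 at -0.87 (SE 0.33). G0s2 was -0.40 without Cnot3+/- 1 and -1.35 without Cnot3+/- 2. Cidea, a lipid droplet gene, stood at 8.09 in wild-type 1 and between 4.39 and 4.67 on the other 3 arrays. Its difference was -1.63 (SE 1.16), and 0.23 without wild-type 1.

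Cholesterol synthesis genes stood higher mainly in Cnot3+/- 2. Of 18 genes, 16 were higher, and the list mean lay 0.04 above wild-type in Cnot3+/- 1 and 0.52 above it in Cnot3+/- 2 (adjusted p = 0.00250 with the preset correlation, adjusted p = 0.703 with an estimated correlation). Wild-type 1 and wild-type 2 lay at -0.12 and 0.12, so Cnot3+/- 1 lay between them. The squalene epoxidase gene Sqle differed by 0.80 (SE 0.61), and by -0.15 without Cnot3+/- 2. The lanosterol synthase gene Lss differed by 0.62 (SE 0.33) on the probe set used, which stood at 4.07 in wild-type 1. It differed by 0.07 on a brighter _s_at probe set and by 0.18 on another dim one. On the probe set used, Lss differed by 0.15 without wild-type 1 and 1.09 without wild-type 2. Macrophage and interferon genes were high on Cnot3+/- 2 too. The list call was lost without Cnot3+/- 2 (adjusted p = 0.719) and without wild-type 1 (0.0921).

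The bile acid synthesis and transport list did not pass, with 11 of 19 genes lower (adjusted p = 0.899). Its transporter Slco1a4 was the member that passed adjusted over the list alone (0.00708). Slco1a1 differed by -0.56 (SE 0.32). It ran from -0.94 without Cnot3+/- 1 to -0.18 without Cnot3+/- 2. Cyp7a1, the rate-limiting enzyme of bile acid synthesis, differed by -0.06 (SE 0.39), with 9.87 in Cnot3+/- 1 and 8.70 in Cnot3+/- 2. Without Cnot3+/- 2 the Cyp7a1 difference was 0.53. Igf1, the growth hormone target, differed by 0.17 (SE 0.17). Its difference was 0.33 without Cnot3+/- 2 and below 0.01 without Cnot3+/- 1.

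Interferon-induced genes were high in Cnot3+/- 2 and close to wild-type in Cnot3+/- 1. Of 25 genes, 22 were higher and 12 had no overlap between the groups. The list mean lay 0.13 above wild-type in Cnot3+/- 1 and 1.48 above it in Cnot3+/- 2 (adjusted p = 6.25e-09 with the preset correlation, adjusted p = 0.703 with an estimated correlation). The chemokine gene Cxcl10 stood between 4.83 and 5.22 on the wild-type arrays and Cnot3+/- 1 and at 8.88 on Cnot3+/- 2, and its difference of 1.91 (SE 1.22) was -0.03 without Cnot3+/- 2. Usp18, which encodes a deconjugase of the ubiquitin-like ISG15, was above wild-type in both Cnot3+/- arrays, at 7.37 and 8.39 against 5.59 and 5.85. It was the member that passed adjusted over the list alone (0.0360). The list call was lost without Cnot3+/- 2 (adjusted p = 0.114).

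Markers of macrophages and of T and NK cells moved with the interferon genes. All 20 Kupffer cell and macrophage markers had a mean above wild-type, but the list lay at -0.26 in Cnot3+/- 1 and 1.63 in Cnot3+/- 2 (adjusted p = 0.000228 with the preset correlation, adjusted p = 0.703 with an estimated correlation). Cd5l, a secreted macrophage gene, differed by 1.16 (SE 0.64), and Marco stood at 6.40 in Cnot3+/- 1 and 9.49 in Cnot3+/- 2. Without Cnot3+/- 2 the list passed in the opposite direction (adjusted p = 0.00110). The 11 T and NK cell markers lay at 0.11 in wild-type 1 and -0.11 in wild-type 2. They lay at -0.05 in Cnot3+/- 1 and 1.19 in Cnot3+/- 2 (adjusted p = 0.0299 with the preset correlation, adjusted p = 0.703 with an estimated correlation). Their members Ccl5 and Gzmb differed by 1.77 (SE 1.21) and 1.13 (SE 0.61), and Ccl5 by -0.15 without Cnot3+/- 2. Without that array Cd5l differed by 0.16 and Gzmb by 0.18, and without Cnot3+/- 1 by 2.17 and 2.07. The T and NK cell call was lost without wild-type 2 (adjusted p = 0.405) and with the lowest 60% of probe sets left out (0.613), and the direction turned without Cnot3+/- 2 (0.881).

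With Cnot3+/- 1 left out, 38 genes were higher at an adjusted p under 0.05. They included Gbp6, Marco, Cxcl10, Ccl5, Usp18 and Cd5l besides Lcn2 and Cox6b2. That count sets 1 array against 2, and the lone array is assumed to vary as the wild-type arrays do.

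Endothelial markers stood lower, mostly in Cnot3+/- 1. All 20 markers had a mean below wild-type and 11 had no overlap between the groups. The list mean lay at -0.92 in Cnot3+/- 1 and -0.17 in Cnot3+/- 2 (adjusted p = 3.08e-10 with the preset correlation, adjusted p = 0.703 with an estimated correlation). Clec4g stood at 9.99 and 10.01 in wild-type, 8.40 in Cnot3+/- 1 and 9.60 in Cnot3+/- 2. Oit3, another sinusoidal endothelial gene, differed by -0.99 (SE 0.23). Emcn, which encodes the endothelial sialomucin endomucin, differed by -0.95 (SE 0.14) and was the member that passed adjusted over the list alone (0.0168); it was named after its values were seen.

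Stellate cell and fibroblast markers went opposite ways in the Cnot3+/- arrays, with list means of -0.39 in Cnot3+/- 1 and 0.44 in Cnot3+/- 2. Their mean difference was 0.02, the median -0.02 and the adjusted p 0.972. The collagen genes Col3a1 and Col1a1 differed by 0.73 (SE 0.58) and 0.46 (SE 0.41), and by -0.15 and -0.16 without Cnot3+/- 2. The list passed downward without Cnot3+/- 2 (adjusted p = 4.37e-08) and upward without Cnot3+/- 1 (1.17e-06).

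**Figure D2:**
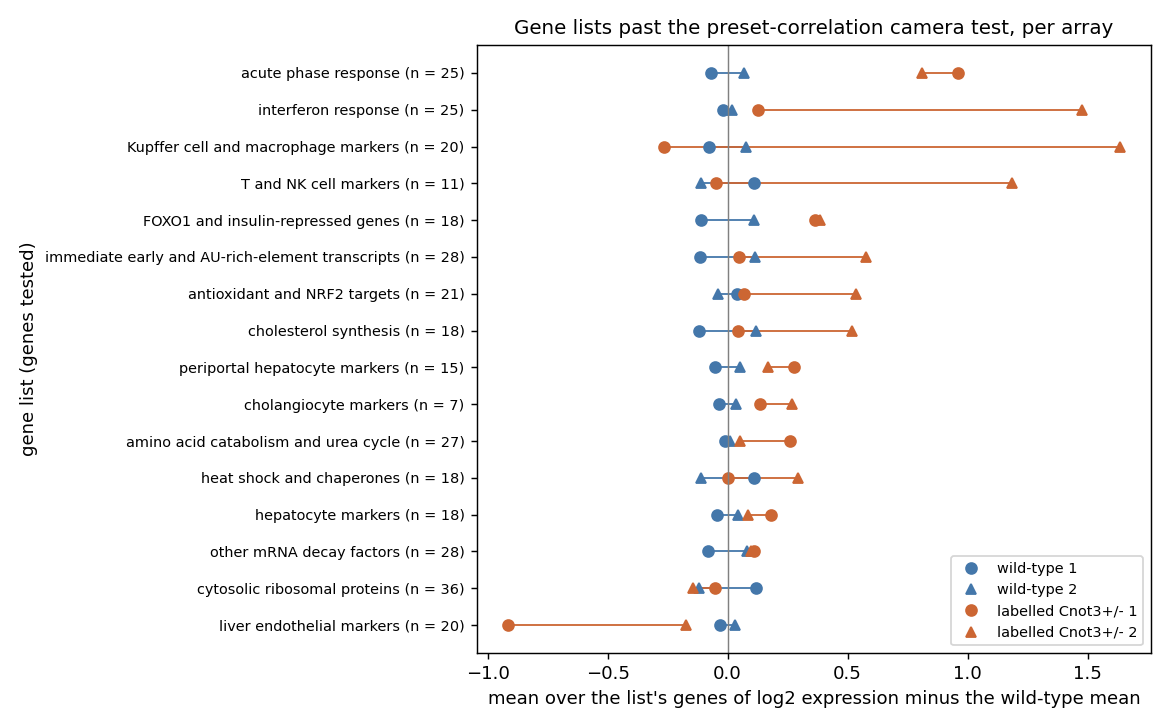
Mean over the genes of each list (vertical axis, number of genes tested in brackets) of log2 expression minus the wild-type mean (horizontal axis), with 1 symbol per array (circles for replicate 1, triangles for replicate 2, blue for wild-type, orange for arrays labelled Cnot3+/-) and lines joining the arrays of a group. The acute phase list lies at 0.96 and 0.81 in the Cnot3+/- arrays, while the interferon list lies at 0.13 and 1.48, and none of the lists passed with an estimated correlation (smallest adjusted p = 0.703).

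Immediate early genes and transcripts with AU-rich elements, which recruit deadenylases, stood higher chiefly in Cnot3+/- 2. Of 28 genes, 22 were higher, with list means of 0.05 in Cnot3+/- 1 and 0.58 in Cnot3+/- 2 (adjusted p = 0.000237 with the preset correlation, adjusted p = 0.703 with an estimated correlation). Wild-type 1 and wild-type 2 lay at -0.12 and 0.12, so Cnot3+/- 1 lay between them. Egr1 differed by 1.32 (SE 0.51), at 6.21 in Cnot3+/- 1 and 7.78 in Cnot3+/- 2 against 5.81 and 5.54 in wild-type. Its difference was 0.54 without Cnot3+/- 2. Macrophage and interferon genes were high on the same array. The call was lost without Cnot3+/- 2 (adjusted p = 0.429) and without wild-type 1 (0.0898).

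Antioxidant genes and chaperones also stood higher chiefly in Cnot3+/- 2. The antioxidant list had 15 of 21 genes higher, with means of 0.07 in Cnot3+/- 1 and 0.54 in Cnot3+/- 2 (adjusted p = 0.0258 with the preset correlation, adjusted p = 0.703 with an estimated correlation). Its largest difference, that of Mt2, ran the other way, at 3.13 above the wild-type mean in Cnot3+/- 1 and 1.46 in Cnot3+/- 2. The heme oxygenase gene Hmox1 differed by 0.98 (SE 0.55). Hmox1 differed by 0.13 without Cnot3+/- 2 and 1.84 without Cnot3+/- 1. Macrophage and interferon genes were high on Cnot3+/- 2 as well. That call was lost without Cnot3+/- 2 (adjusted p = 0.980), without wild-type 1 (0.0606) and without wild-type 2 (0.243). The chaperone list had 14 of 18 genes higher, with means of 0.002 in Cnot3+/- 1 and 0.29 in Cnot3+/- 2 (adjusted p = 0.0364 with the preset correlation, adjusted p = 0.703 with an estimated correlation). Wild-type 1 and wild-type 2 lay at 0.11 and -0.11 for this list, so Cnot3+/- 1 lay between them. Hspa1a and Hspa1b, near-identical genes that probe sets may not tell apart, differed by 0.64 (SE 0.37) and 0.64 (SE 0.45). They differed by 0.19 and 0.07 without Cnot3+/- 2, and by 1.10 and 1.22 without Cnot3+/- 1. The chaperone call was lost without Cnot3+/- 2 (adjusted p = 0.823), without wild-type 2 (0.694) and with the lowest 60% of probe sets left out (0.107).

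Amino acid catabolism genes and general hepatocyte markers stood slightly higher, more so in Cnot3+/- 1. The amino acid catabolism and urea cycle list had 21 of 27 genes higher, with means of 0.26 in Cnot3+/- 1 and 0.05 in Cnot3+/- 2 (adjusted p = 0.00518 with the preset correlation, adjusted p = 0.703 with an estimated correlation). The argininosuccinate synthase gene Ass1 differed by 0.71 (SE 0.22) and the branched-chain ketoacid dehydrogenase gene Bckdhb by 0.63 (SE 0.14). Ass1 differed by 0.43 without Cnot3+/- 1. Endothelial markers were low on the same array. The call was lost without Cnot3+/- 1 (adjusted p = 0.611). General hepatocyte markers had 13 of 18 genes higher, with means of 0.18 in Cnot3+/- 1 and 0.09 in Cnot3+/- 2 (adjusted p = 0.0318 with the preset correlation, adjusted p = 0.703 with an estimated correlation). Their call was lost without Cnot3+/- 1 (adjusted p = 0.381), without wild-type 1 (0.239) and with the lowest 60% of probe sets left out (0.0640).

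Periportal hepatocyte markers had 11 of 15 genes higher, with means of 0.28 in Cnot3+/- 1 and 0.17 in Cnot3+/- 2 (adjusted p = 0.0105 with the preset correlation, adjusted p = 0.703 with an estimated correlation). Adjusted over the list alone, Aldh1b1, a mitochondrial aldehyde dehydrogenase gene, passed at 1.16 (SE 0.20) and Ctsc, the cathepsin C gene, at 0.89 (SE 0.16). Endothelial markers were low on Cnot3+/- 1, at -0.92. The list call was lost without wild-type 1 (adjusted p = 0.0898) and without Cnot3+/- 1 (0.229). Cholangiocyte markers had 6 of 7 genes higher, with means of 0.14 in Cnot3+/- 1 and 0.27 in Cnot3+/- 2 (adjusted p = 0.0178 with the preset correlation, adjusted p = 0.703 with an estimated correlation), with Epcam at 0.40 (SE 0.18) and Prom1 at 0.39 (SE 0.14). Epcam was 0.24 without Cnot3+/- 2. The cholangiocyte call was lost without wild-type 1 (adjusted p = 0.0921) and without Cnot3+/- 2 (0.146).

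Cytosolic ribosomal protein genes had 31 of 36 members lower by a small amount. The mean difference was -0.10, with the wild-type arrays at 0.12 and -0.12 and the Cnot3+/- arrays at -0.05 and -0.14 (adjusted p = 0.0299 with the preset correlation, adjusted p = 0.719 with an estimated correlation). Rpl12 differed by -0.47 (SE 0.27) and Rpl14 by -0.40 (SE 0.26), both on probe sets of low signal. Rpl12 was -0.10 without Cnot3+/- 1 and Rpl14 was -0.05 without wild-type 1. The call was lost after quantile normalization (adjusted p = 0.0541) and without Cnot3+/- 2 (0.589), and the direction turned without wild-type 1 (0.674).

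In all, 14 of the 45 lists passed upward and 2 downward with the preset correlation, 6 and 3 without wild-type 1, and 8 and 6 without Cnot3+/- 2. None passed with an estimated correlation, where the acute phase list alone had an unadjusted p under 0.05, or with limma's fry test (smallest adjusted p = 0.234, 2 lists at an unadjusted p under 0.05). In the simulation, the acute phase list raised by 0.5 on both Cnot3+/- arrays reached an unadjusted camera p of 0.00801 with an estimated correlation. That is before adjustment over 45 lists. Failing this test is therefore weak evidence against a list, and it leaves the preset calls without backing. Lists of lysosome and autophagy genes (adjusted p = 0.0543), endoplasmic reticulum stress (0.0560) and the circadian clock (0.0718) did not pass. Neither did pancreas acinar (0.104), adipocyte (0.122), skeletal muscle (0.295) and red blood cell markers (0.410). The lists of energy expenditure, male-biased liver genes and the integrated stress response each had an adjusted p of 0.544, and cytochrome P450 genes one of 0.947. The medians of the cytochrome P450 and male-biased lists were -0.01 each, with means just above 0.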

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

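Values of single lists under settings other than the estimated correlation and fry were computed only after the results were seen. Lcn2 and Cox6b2 passed with no filter and with the 60% filter, under both scalings, with probe sets averaged or tested singly, and with a trended or robust prior. At an adjusted p under 0.01, 1 gene passed. Without moderation 1 gene, Tmem87a, passed upward and 1, Ncbp3, downward, both named after their values were seen. With the replicate number as a replicate block, 0 genes passed (adjusted p = 0.266 for Lcn2 and Cox6b2) and 15 lists were higher and 4 lower, among the latter fatty acid synthesis (adjusted p = 0.0431) and glycolysis (0.0393), which had not passed. Same-numbered arrays deviated with a correlation of 0.159 over 2 pairs, and the labels give the number no further meaning. Leaving out 1 array costs 1 of the 2 residual degrees of freedom, and the lone array is assumed to vary like the others. With an array left out, non-overlap of the groups is also easier to reach by chance. The number of genes higher then ran from 0 to 38, of genes at least 2-fold higher without overlap from 39 to 289, and of those lower from 15 to 66. The number of lists higher ran from 6 to 14 and of lists lower from 3 to 6. There were 2 lists lower with no filter, 5 with the 60% filter, 1 after quantile normalization and 6 with probe sets averaged. With an estimated correlation 0 lists were higher and 0 lower, and with fry 0 and 0. The median difference of all genes was -0.009, and -0.029 after quantile normalization. Signal near background limits the dim genes, which the filters change. Other causes were not tested.

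Of the values of the 87 named genes under the alternatives, 1087 kept their direction and side of the threshold, 8 lost a call (Lcn2 and Cox6b2 without moderation, under the block and without either wild-type array) and 6 gained one, all without Cnot3+/- 1. With 1 array left out, 50 of these genes moved by over 1.5 times or turned. Of the values of the lists, 300 kept both, 58 lost a call and 24 gained one. Gene differences that turned, none of them past the threshold with all 4 arrays, were these. The Cnot3 difference was 0.0398 with probe sets averaged and ran from -0.36 to 0.30 with an array left out. Angptl4 was -0.0138 with no filter, Fgf21 -0.0196 after quantile normalization and Cpt1a -0.0259 with probe sets averaged. With an array left out, Angptl4 ran from -0.0641 to 0.126, Fgf21 from -0.57 to 0.60, G6pc from -0.0219 to 0.553, Cyp7a1 from -0.65 to 0.53 and Pdk4 from -0.26 to 2.57. Cidea ran from -3.48 to 0.23, Acot3 from -1.29 to 0.0669, Sqle from -0.15 to 1.75, Cxcl10 from -0.0273 to 3.85 and Ccl5 from -0.15 to 3.68, the last 2 past the threshold at their upper ends. S100a8 ran from -0.0359 to 1.70, Col3a1 from -0.15 to 1.61 and Col1a1 from -0.16 to 1.08. The cause was not tested.

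Lists that turned direction are given by adjusted p. With no filter these were the TCA cycle (0.984), lipid droplets (0.995), bile acid (0.984) and B cell (0.995) lists. The TCA cycle also turned with probe sets averaged (0.950) and the bile acid list under the replicate block (0.824). Stellate cell markers turned with the 60% filter (0.613), centring (0.946), the block (0.985) and fry (0.989). With an array left out, adjusted p ran from 0.000126 to 0.674 for ribosomal proteins, 0.212 to 0.476 for the TCA cycle, 0.000113 to 0.934 for fatty acid synthesis, 0.0721 to 0.937 for bile acids and 4.37e-08 to 0.998 for stellate cells. It ran from 0.000944 to 0.589 for fatty acid oxidation, 0.146 to 0.920 for lipid droplets, 4.56e-33 to 0.0243 for macrophages and 3.95e-07 to 0.881 for T and NK cells. For oxidative phosphorylation it ran from 0.0142 to 0.886, for proliferation from 1.89e-05 to 0.724 and for collagen from 3.95e-07 to 0.245. The cause was not tested.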

Other observations

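The tests of explanations in this part were chosen only after the results were seen. Cell cycle and matrix genes were higher in Cnot3+/- 2 without passing as lists. The proliferation list had 12 of 19 genes higher, with means of -0.07 in Cnot3+/- 1 and 0.60 in Cnot3+/- 2 (camera adjusted p = 0.206). Ccnb2, a mitotic cyclin gene, differed by 1.56 (SE 0.47) and Cdc20, an activator of the anaphase-promoting complex, by 0.83 (SE 0.44). Ccnb2 and Cdc20 differed by 0.88 and 0.16 without Cnot3+/- 2, and by 2.25 and 1.497 without Cnot3+/- 1. Macrophage, T and NK cell and interferon lists were high on Cnot3+/- 2 too, at 1.63, 1.19 and 1.48. That list passed without Cnot3+/- 1 (adjusted p = 1.89e-05) and with no filter on dim probe sets (0.00644), and turned downward without Cnot3+/- 2 (0.391). The collagen and fibrosis list lay at -0.21 in Cnot3+/- 1 and 0.47 in Cnot3+/- 2 (adjusted p = 0.120), with Col5a2 at 0.96 (SE 0.19). It passed upward without Cnot3+/- 1 (adjusted p = 3.95e-07) and with no filter (0.0355), and downward without Cnot3+/- 2 (0.00782). In the p53 target list 11 of 17 genes were higher (adjusted p = 0.164), with Trp53inp1 at 0.66 (SE 0.25). Trp53inp1 was 0.36 without wild-type 1. It passed without Cnot3+/- 1 (adjusted p = 0.0162) and with no filter (0.0483).

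Secreted liver factors moved both ways. The list of IGF-binding proteins and hepatokines had 14 of 23 genes higher (adjusted p = 0.270), and 3 members passed adjusted over the list alone. Besides Igfbp1 these were Angptl8, an inhibitor of lipoprotein lipase that feeding raises, at -0.72 (SE 0.16), and the activin antagonist gene Fst at 0.68 (SE 0.13), named after its values were seen. The lipoprotein lipase gene Lpl differed by 1.48 (SE 0.31), at 7.70 and 7.02 in wild-type and 8.53 and 9.15 in the arrays labelled Cnot3+/-. Lpl and Rtn4, at 0.66 (SE 0.18), led the female-biased list, which had 8 of 16 genes higher (adjusted p = 0.401) and a median of -0.02 against a mean of 0.10. Among pericentral hepatocyte markers 10 of 17 were higher (adjusted p = 0.206), with list means of 0.02 in Cnot3+/- 1 and 0.25 in Cnot3+/- 2. The glutamate transporter gene Slc1a2, at 0.95 (SE 0.18), passed adjusted over the list alone (0.0468), and the ammonium transporter gene Rhbg differed by 0.76 (SE 0.28). Rhbg differed by 0.37 without Cnot3+/- 2 and 1.14 without Cnot3+/- 1. The B cell list did not pass (adjusted p = 0.544), with a median of -0.08 and a mean of 0.16. Its immunoglobulin genes Ighm and Jchain differed by 0.98 (SE 0.35) and 0.85 (SE 0.20). Ighm differed by 0.49 without wild-type 1 and 1.48 without wild-type 2.

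The interferon and macrophage lists were high in Cnot3+/- 2 and not in Cnot3+/- 1. The interferon list lay at 0.128 (SE 0.077 over genes) in Cnot3+/- 1 and at 1.48 in Cnot3+/- 2, and with 1 array each these values do not exclude a genotype effect of the same size in both mice, since the spread between animals is not in that SE. A lower share of hepatocytes would raise the markers of every other cell type alike. In Cnot3+/- 2 macrophage markers exceeded endothelial markers, which lay at -0.17, by 1.81 (SE 0.162 over genes). These markers did not rise alike on this array. With 1 array, and an SE that leaves out the spread between animals, the values do not decide on this explanation. More macrophages in that liver sample stay open as a hypothesis, because the mean of the 20 macrophage markers there, 1.63 (SE 0.143), is part of the pattern itself and is no separate test. An infection or injury of that animal, and a genotype effect that varies between animals, stay open and were not tested.

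Acute phase genes were high in both Cnot3+/- arrays, by 0.88 on average. The other neutrophil markers had a mean difference of 0.0911 (SE 0.132 over genes) against 4.22 for Lcn2, so as a set they did not rise as Lcn2 did. That SE leaves out the spread between animals. Among these markers S100a8 was dim, at 4.38 and 3.74 in wild-type, where RMA shrinks differences. Neutrophils as the source of Lcn2 therefore stay open. After quantile normalization the list still differed by 0.870 (SE 0.236 over genes). RMA had already normalized the values across arrays, so a further step could change little and does not decide on array scaling. Of the 3 splits of the 4 arrays, 1, the real one, gave a difference as large, and the highest other was 0.142; 3 splits are too few for a share under 0.05. A genotype effect and a difference in the animals' health, litter or handling stay open, and these data do not separate them.

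Cox6b2, which passed along with Lcn2, lies near Cnot3, which raises the hypothesis of an effect on the chromosomal neighbourhood, such as sequence carried along with the altered allele. The window around Cnot3 held 10 tested genes before it and 50 after it, and 4 of its 59 genes other than Cox6b2 had an unadjusted p under 0.01. These were Nlrp12, Cdc42ep5 at 1.31 (0.86 without wild-type 2), Peg3 at 0.82 and Zim3 at -0.60, named after their values were seen, and 0 of 12130 other windows of equal size held as many. Successive windows were shifted by 1 gene, so they overlap and are not independent. Peg3 and Zim3 are next to each other, 47 and 48 tested genes from Cnot3. At an unadjusted p under 0.05 the window held 5, and 951 windows (7.84%) held as many, so the thresholds give different answers and the hypothesis stays open. The labels do not describe the allele, and a strain variant under the probes was not tested.

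The count of 2 genes past the threshold was reached in 1 of the 3 splits of the 4 arrays, the real one, and the highest other split gave 0; 3 splits are too few for a share under 0.05. At an unadjusted p under 0.05 the real split gave 480 genes, the split by replicate number 969 and the remaining split 279.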
